A study of Homo sapiens with 8 samples.

How the data were processed

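Human 293T cells carrying a Halo-tagged PTB or a Halo-tagged YFP were either crosslinked with UVC or UVA light or left without UV. The tagged protein was then captured on beads with its RNA and libraries were made by an iCLIP-type procedure, per the labels' protocols. Libraries were sequenced on either of 2 Illumina platforms, per the labels, which do not say which library went on which. The titles of the labels put 2 samples in each of 4 groups. Each group has 1 peak list without replicate names, so the replicates were pooled or merged before deposit, in a way not given in the sources used here. The list of published PTB iCLIP peaks covers all samples of an earlier study and was made by the submitters with the same methods, per the series text, which does not name its cells.

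Reads were mapped with Bowtie 1.1.2, and the builds hg19 and dm3 were named, per the submitters' processing notes. Chromosome names are human, and some chromosome 1 peaks in the UVC, UVA and iCLIP lists lie past the last gene of that chromosome in the newer GRCh38 build, so positions were read as hg19. The role of dm3, the peak caller and its filters are not given in the sources used here. The deposited lists have 10 columns and no header. The start and end are deposited as positions counted from 0 and were written 1-based. The deposited p-value of each peak is printed to 14 decimals, and none was above 0.05. The deposited score of column 7 was taken as limited to 1000. It was checked on peaks with a printed p-value above 0. Of these, 99.9% in UVC, 97.6% in UVA and 98.5% in iCLIP scored 10 times the negative log10 of that p-value, rounded down. The 1429 UVC, 31203 UVA and 8554 iCLIP peaks with a printed p-value of 0 could not be checked in this way, nor could the limit. Peaks listed with a p-value of 0 and a score of 0 (148 UVC, 538 UVA, 104 iCLIP and 39 YFP peaks) were taken as lying at the score limit, since the logarithm of 0 cannot be formed. Column 5 holds the constant 200 and was not used. Depth per sample is unknown.

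From these lists the number of peaks, the nucleotides covered on each strand, widths, scores and shares per chromosome were counted. Peaks within 20 nt of each other on the same strand were merged into sites, because many peaks touched: 30.2% of plus-strand and 9.08% of minus-strand UVC intervals ended where the next began. Merged sites keep the highest score of their peaks. Lists were compared by overlap of at least 1 nt on the same strand. The share shared was given with an exact Clopper-Pearson 95% interval and set against 100 copies of the second list, in which every peak was moved by its own random distance of 500 to 5000 nt in either direction. For sites in all 3 PTB lists the UVC sites were moved. Differences between shares carry a normal 95% interval, and ratios of chromosome shares a normal 95% interval on the log scale. Intervals of the weighted UVC share and of the gap it closes came from binomial resampling of the UVC score bands, with the UVA values held fixed. All intervals cover counting error only, and no p-value is given for a difference between conditions, since each group is a single list. The intervals also treat peaks as independent, although many peaks touched and some intervals were listed repeatedly. Such repeats numbered 2192 in UVC, 555 in UVA, 575 in iCLIP, 157 in no UV and 111 in YFP. The intervals may therefore be too narrow. The peaks named were fixed by rule before the data were examined: the 5 with the highest deposited score in each list. Scores were tied at the limit in 4 lists, and ties were ranked by width and then position, a rule added later. The windows, score bands, widths and sites in both controls were chosen after the data had been seen.

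The overlap counts were checked against bedtools 2.31.1, which gave the same number of shared peaks in 20 of 20 ordered pairs. The comparison with moved copies was tested on simulated data: with the PTB UVC list as target and 20% of 20000 simulated peaks placed on it, 19.6% was recovered above the moved copies, and with 0% placed the value was -0.073%. The simulated peaks not placed on the list were scattered and did not cluster with it. The simulation therefore cannot show whether moved copies account for local clustering that 2 lists share. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

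Alternatives set before the data were examined were coverage of at least 50% of the peak, midpoints within 50 nt, peaks at or above the median score, strand ignored, chromosomes 1 to 22 and X only, peaks within 20 nt merged, moves of 100 to 500 nt and of 5000 to 50000 nt, and equal numbers of top peaks. In the midpoint setting, the midpoint of the counted peak had to lie in a peak of the second list or within 50 nt of its ends. Alternatives added afterwards left out peaks found in a control, kept scores of at least 100, or kept sites wider than 50 nt, and chromosome shares were also taken among peaks scoring above 100. Control overlaps were also taken in the same top share of each list by score, with ties kept. Genes, exons and introns, pyrimidine motifs, splice-site distances and the planned gene lists were not analysed here, since no hg19 sequence or annotation was used. For the same reason, of the rule for named genes only the part on peaks was applied.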

Results

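Crosslinking and immunoprecipitation (CLIP) maps where an RNA-binding protein touches RNA in living cells. The study profiled a Halo-tagged polypyrimidine tract binding protein (PTB), a splicing regulator that binds pyrimidine-rich RNA, with a gel-free CLIP protocol called GoldCLIP. The cells were 293T, a human embryonic kidney line. The Halo tag, a protein tag that bonds covalently to a bead-bound ligand, was used to pull down the protein with its RNA. The 8 samples fall into 4 groups of 2: PTB crosslinked with UVC, PTB crosslinked with UVA, PTB without UV, and Halo-tagged yellow fluorescent protein (YFP) crosslinked with UVC. Each group has 1 pooled peak list, and a further list holds PTB peaks that the submitters re-derived from a published iCLIP study, iCLIP being an earlier, gel-based form of the assay. All positions are in hg19. The lists give no read numbers, so sequencing depth is unknown, and no spread between replicates can be given for any value. Regions are named by position and strand only.

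PTB crosslinked with UVC gave 118434 peaks covering 3624.78 kb, and PTB crosslinked with UVA gave 83725 peaks covering 3474.14 kb. PTB without UV gave 3809 peaks over 115.686 kb, and YFP with UVC gave 2136 peaks over 99.349 kb. The UVC list of PTB therefore held 31.1 times as many peaks as the list without UV and 55.4 times as many as the YFP list. For UVA the corresponding ratios were 21.98 and 39.2. Against YFP the ratio depended on the measure: it was 74.6 by merged sites and 36.5 by nucleotides covered for UVC, and 64.9 and 34.97 for UVA. Against no UV it was 34.4 and 31.3 for UVC, and 29.9 and 30.03 for UVA. The iCLIP list held 58213 peaks over 2508.58 kb. After peaks within 20 nt on the same strand were merged into sites, the PTB UVC list fell to 80531 sites, the UVA list to 70110 and the iCLIP list to 52446, and the controls to 2341 (no UV) and 1080 (YFP). The lead of UVC over UVA was 1.41-fold by peaks, 1.15-fold by sites and 1.04-fold by nucleotides covered. These are counts from single pooled lists without a test, and they depend on depths that the lists do not give.

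**Figure D1:**
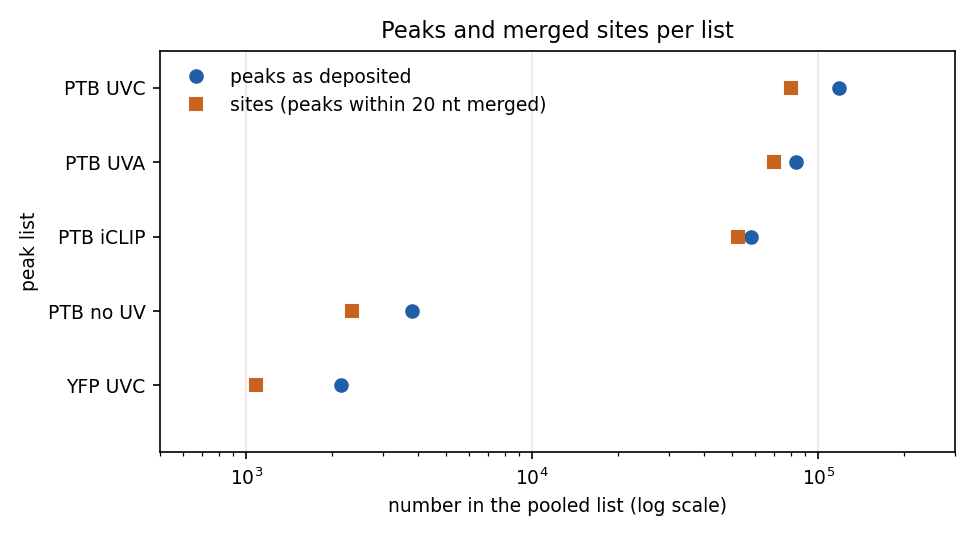
Number of deposited peaks (circles) and of sites after merging peaks within 20 nt (squares) in each of the 5 pooled lists, on a log axis. The 3 PTB lists made with crosslinking hold between 52446 and 80531 sites, the controls 2341 and 1080.

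The deposited scores, which belong to the authors' peak calling and rise as the p-value of a peak falls, differed in range between the lists. The median score was 92 in the PTB UVA list, 47 in the iCLIP list and 19 in the PTB UVC list, against 17 in each control. Peaks scoring above 100 made up 47.3% of the UVA list, 24.0% of the iCLIP list, 1.93% of the UVC list, 1.39% of the list without UV and 13.4% of the YFP list. Since a p-value depends on depth, scores rank peaks within a list and do not measure binding between lists.

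The comparison of PTB with its controls asked how much of the PTB lists lay where RNA was also recovered without crosslinking or without PTB. The control lists, whose depth is unknown, are short, which keeps these shares small. If every control peak met 1 PTB peak, 3.22% (no UV) and 1.80% (YFP) of PTB UVC peaks and 4.55% and 2.55% of UVA peaks would be shared. These values are not strict limits, since a control peak can meet more than 1 PTB peak: 603 no-UV peaks met 735 UVC peaks. Of the PTB UVC peaks, 735 (0.621%, exact 95% interval 0.577 to 0.667) shared at least 1 nt on the same strand with a peak of the list without UV. That was 8.85 times the mean share of 0.0701% in 100 copies of the control list whose peaks had been moved by random distances. For the YFP list 724 PTB UVC peaks were shared (0.611%, interval 0.568 to 0.657), 9.77 times the moved copies. Of the PTB UVA peaks, 500 (0.597%, interval 0.546 to 0.652) were shared with the list without UV, 5.74 times the moved copies, and 472 (0.564%) with the YFP list. The ratios depended on how far the copies were moved. With moves of 100 to 500 nt they were 4.18 (UVC in no UV), 5.53 (UVC in YFP) and 2.39 (UVA in no UV), and with moves of 5000 to 50000 nt they were 25.5, 35.5 and 20.8. Intervals of unweighted shares here and below are exact (Clopper-Pearson), and those of differences and of chromosome ratios are normal. All cover counting error only and treat peaks as independent, which repeated and touching peaks are not. Counted on merged sites the UVC share in the YFP list was 0.348%, and among peaks at or above the median score it was 1.02%. The UVA share in the list without UV was 0.364% when at least 50% of the peak had to be covered. It was 0.926% when the midpoint of the UVA peak had to lie within 50 nt of a peak of that list.

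Seen from the controls, the shared part was larger. PTB UVC peaks overlapped 15.8% of the peaks found without UV (interval 14.7 to 17.0) and 25.1% of the YFP peaks (interval 23.3 to 27.0). PTB UVA peaks overlapped 12.6% and 21.3% of them, and iCLIP peaks 6.17% and 9.22%. The controls also met each other: 135 of the peaks without UV (3.54%, interval 2.98 to 4.18) lay on a YFP peak, 12.5 times the moved copies, or 5.57 and 79.4 times with the shorter and longer moves. In the other direction 7.77% of YFP peaks were shared, or 4.82% when at least 50% of the peak had to be covered. Merging gave 70 sites present in both controls. PTB UVC peaks lay on 64 of these sites, PTB UVA peaks on 43 and iCLIP peaks on 23, and 20 sites were present in all 5 lists. The site with the highest score without UV, chromosome 1 from 11968230 to 11968294 on the plus strand, was among these 20. So were plus-strand sites on chromosome 1 from 28833874 to 28834042 and from 28835070 to 28835231, and on chromosome 6 from 52860647 to 52860709. Minus-strand sites on chromosome X from 73047176 to 73047287 and on chromosome 11 from 62609163 to 62609273 were also among them.

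**Figure D2:**
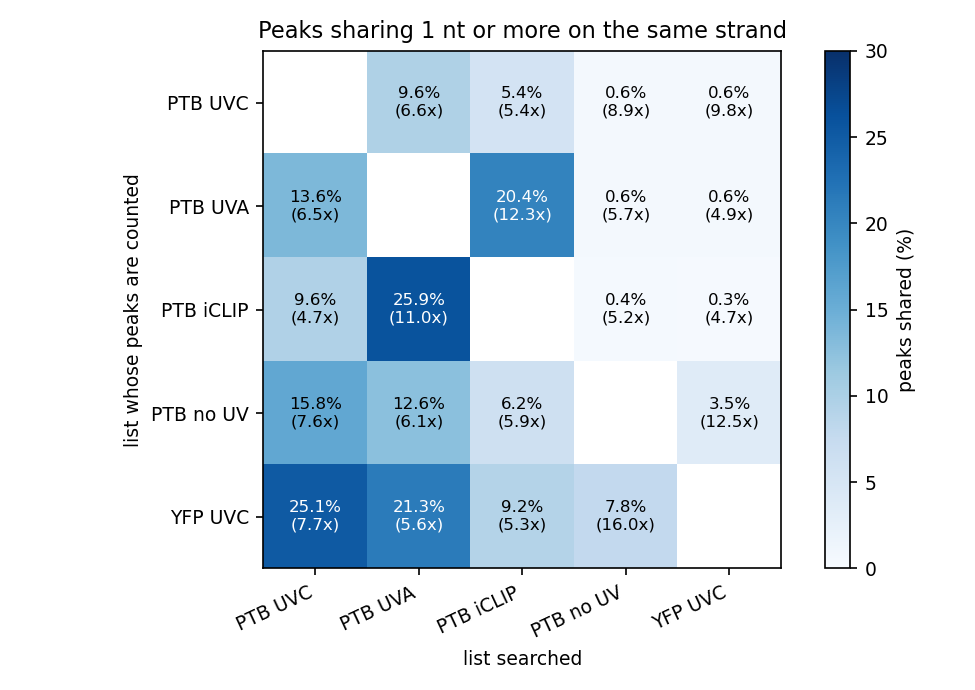
Share of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 1 nt on the same strand, in percent, with the ratio to the mean of 100 randomly moved copies in brackets. The iCLIP list against the UVA list has the highest share, 25.9%.

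The highest-scoring peaks of the PTB UVC list lay at control positions more often than those of the other PTB lists. In the top 3.36% of each list by score, 18.7% of UVC peaks (interval 17.5 to 19.9), 8.73% of UVA peaks (interval 7.72 to 9.84) and 4.88% of iCLIP peaks (interval 3.97 to 5.92) overlapped a control peak. In the top 10% the shares were 7.02%, 4.56% and 2.23%. In the top 50% UVC and UVA were close, at 1.75% (interval 1.65 to 1.86) and 1.63% (interval 1.51 to 1.75), and iCLIP was at 0.847%. The score limit of 1000 takes in 0.217% of the UVC list and 3.36% of the UVA list. At this limit, 234 of 257 PTB UVC peaks (91.1%, interval 86.9 to 94.2) overlapped a control peak, as did 246 of 2817 PTB UVA peaks and 67 of 265 iCLIP peaks (25.3%, interval 20.2 to 31.0). The UVC share rose with the score, from 0.221% at scores up to 16 to 11.9% between 100 and 200, and above 500 but short of the limit 93 of 155 UVC peaks lay on a control peak. Of the 5 named PTB UVC peaks, which were tied at the limit and ranked by width, 3 lay on a control peak: chromosome 12 from 49521569 to 49521683 (minus strand), chromosome 13 from 27829537 to 27829636 (plus) and chromosome X from 73059077 to 73059159 (minus). The other named UVC peaks, on chromosome 17 from 37360869 to 37360972 (plus) and on chromosome X from 107964804 to 107964893 (minus), lay on none. None of the 5 named UVA peaks and none of the 5 named iCLIP peaks lay on a control peak. The score bands and top shares were set after the data had been seen.

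The UVA and UVC arms put the same tagged protein through different crosslinking wavelengths. Which platform each library ran on is not given, so a platform difference between the arms, if any, cannot be told apart from wavelength. The arms shared part of their positions. Of the PTB UVA peaks, 11388 (13.6%, interval 13.4 to 13.8) overlapped a PTB UVC peak, 6.54 times the mean of 2.08% in moved copies. In the other direction 11386 PTB UVC peaks (9.61%, interval 9.45 to 9.78) overlapped a UVA peak, 6.64 times the moved copies. For the UVA peaks the ratio was 2.59 with moves of 100 to 500 nt and 18.1 with moves of 5000 to 50000 nt. With the main moves, the ratios against the much shorter control lists were 8.85 (no UV) and 9.77 (YFP) for UVC peaks, and 5.74 and 4.94 for UVA peaks. The ratios alone therefore do not set the overlap of the PTB arms apart from their overlap with the controls. No moved copy reached the observed share in any of the 20 ordered pairs of lists. The share of UVA peaks in the UVC list was 8.60% when at least 50% of the peak had to be covered, 9.42 times the moved copies. Limiting both lists to scores of at least 100, a limit chosen after the data had been seen, left 2306 UVC peaks to meet and gave a share of 3.47%, which was 10.8 times the moved copies.

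The UVA and UVC lists also differed in where along the genome their sites fell. Chromosome 19 held 8.70% of the UVA sites, 6.46% of the iCLIP sites and 4.20% of the UVC sites, a UVA to UVC ratio of 2.07. The ratio was also above 1 on chromosomes 16 (1.79), 22 (1.41), 17 (1.39) and 11 (1.26), and it was lowest on chromosomes 18 (0.588), 13 (0.596) and 4 (0.650). Counted on peaks in place of sites the ratios were 2.12 on chromosome 19, 1.22 on chromosome 11 and 0.591 on chromosome 18. Peaks scoring above 100 were 2280 (1.93%) of the UVC list and 39589 (47.3%) of the UVA list. This cutoff therefore kept unlike parts of the lists. In the score bands above 100, from 11.9% to 91.1% of UVC peaks lay on a control peak, against 0.852% to 8.73% of UVA peaks. Among peaks scoring above 100 part of the chromosome pattern changed, and whether peaks at control positions account for this was not tested. The ratio stayed above 1 on chromosomes 19 (1.52, interval 1.30 to 1.77) and 16 (1.65, interval 1.27 to 2.14) and below 1 on chromosomes 13 (0.630, interval 0.473 to 0.839) and 6 (0.794, interval 0.659 to 0.957). It turned below 1 on chromosome 11 (0.827, interval 0.698 to 0.981) and above 1 on chromosomes 15 (1.39, interval 1.06 to 1.81) and 5 (1.21, interval 1.004 to 1.46). On chromosomes 20 and X, at 0.976 and 1.02 over all sites, it was 0.670 (interval 0.538 to 0.835) and 0.458 (interval 0.392 to 0.534). Chromosome 18, lowest over all sites, was at 1.44 with an interval that held 1 (0.974 to 2.12, 26 UVC peaks), as did the intervals of the remaining chromosomes. UVA sites lay closer together, with a median distance of 1775 nt to the next site on the same strand against 2617 nt for iCLIP and 4593 nt for UVC. The next site was within 200 nt for 24.3% of UVA, 22.9% of iCLIP and 8.21% of UVC sites. In windows of 100 kb the minus-strand window of chromosome 6 from 97600001 to 97700000 held the most UVC sites (52, against 28 for UVA and 21 for iCLIP). On chromosome 19, the minus-strand window from 9000001 to 9100000 held 8 UVC sites, 56 UVA sites and 19 iCLIP sites. The plus-strand window of chromosome 12 from 53800001 to 53900000 held 25 UVC, 58 UVA and 30 iCLIP sites. Windows and chromosomes were ranked after the data had been seen.

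The iCLIP list allows the gel-free lists to be set against a published gel-based map of the same protein, with peaks made in the same way per the series text. The UVA list shared more with it than the UVC list did. Of the iCLIP peaks, 15085 (25.9%, interval 25.6 to 26.3) overlapped a PTB UVA peak and 5582 (9.59%, interval 9.35 to 9.83) a PTB UVC peak, which were 11.02 and 4.70 times the moved copies. With moves of 100 to 500 nt these ratios were 3.39 and 2.22, and with moves of 5000 to 50000 nt 29.7 and 10.5. The difference was 16.3 percentage points (interval 15.9 to 16.8). From the GoldCLIP side 20.4% of UVA peaks and 5.45% of UVC peaks overlapped an iCLIP peak, a difference of 14.9 points (interval 14.6 to 15.2). Of the iCLIP peaks 0.369% lay on a peak without UV and 0.335% on a YFP peak. These were 5.16 and 4.74 times the moved copies of the much shorter control lists, beside 4.70 for UVC. From the control side 6.17% of no-UV and 9.22% of YFP peaks lay on an iCLIP peak. The iCLIP share in the UVC list was 5.48% when at least 50% of the peak had to be covered, 7.25 times the moved copies. Between peaks scoring at least 100 it was 2.497%, with 2306 UVC peaks to meet, and 15.8 times the moved copies.

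Within bands of the deposited score, which need not mark the same binding in both lists, the UVA and UVC shares came closer. At scores above 100 and up to 200, 23.5% of UVA and 22.8% of UVC peaks overlapped an iCLIP peak, a difference of 0.730 points (interval -1.63 to 3.09), and from there up to 500 the shares were 31.3% and 29.8% (interval of the difference -2.38 to 5.38). The difference was above 0 from 51 to 100 (17.4% and 15.6%), from 31 to 50 (11.6% and 8.65%) and from 21 to 30 (6.20% and 4.65%, interval of the difference 0.964 to 2.13). It was widest above 500 and short of the limit, where 41.2% of 5149 UVA peaks and 21.9% of 155 UVC peaks were shared, and at the score limit, where 55.7% and 43.2% were shared. In these bands most UVC peaks lay on a control peak (60% and 91.1%), against 2.43% and 8.73% of UVA peaks. At scores up to 16 the shares were 2.94% and 3.30%, and from 17 to 20 they were 4.66% and 5.14%, with intervals of the difference that hold 0.

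**Figure D3:**
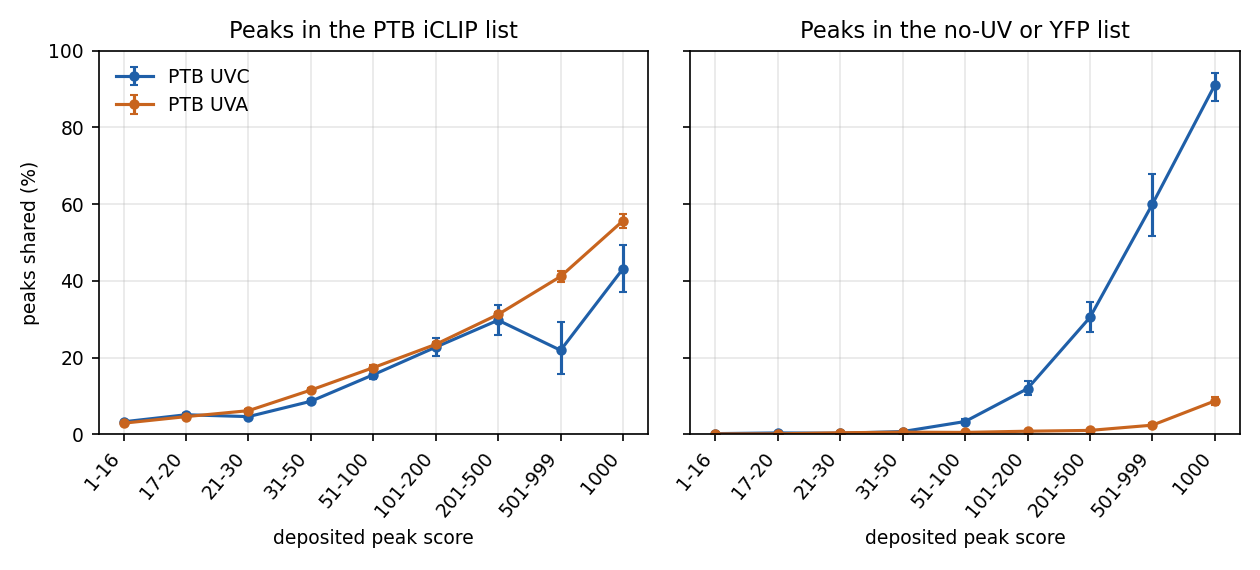
Share of PTB UVC and PTB UVA peaks, in percent with exact 95% intervals, that overlap the iCLIP list (left) or either control list (right), by band of the deposited score. At the score limit 43.2% of UVC and 55.7% of UVA peaks lie on an iCLIP peak, and 91.1% and 8.73% on a control peak. Peaks listed with a p-value and score of 0 (148 UVC and 538 UVA) are counted at the limit by assumption.

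A set of 2875 UVC sites (3.57%) overlapped both a UVA and an iCLIP site, where copies with the UVC sites moved held 303.1 on average and 346 at most. Of these, 2755 lay on no control peak and 120 did. A further 6185 UVC sites overlapped the UVA list alone and 2159 the iCLIP list alone, and 69312 (86.1%) overlapped neither. The widest of the shared sites on no control peak were on chromosome 6 from 27100981 to 27101275 (plus strand, 295 nt), on chromosome 12 from 6879767 to 6880053 (plus, 287 nt) and on chromosome 20 from 5095612 to 5095871 (minus, 260 nt). Among named UVA peaks, those on chromosome 11 from 65765039 to 65765261 (minus), chromosome 17 from 41009033 to 41009236 (plus), chromosome 16 from 68333694 to 68333871 (minus) and chromosome 5 from 154255521 to 154255686 (plus) overlapped peaks of both other PTB lists. The named UVA peak on chromosome 12 from 76426549 to 76426723 (minus) overlapped an iCLIP peak and no UVC peak. Among named iCLIP peaks, those on chromosome 7 from 27208386 to 27208577 (minus), chromosome 9 from 116170050 to 116170232 (minus), chromosome 1 from 156307649 to 156307825 (minus) and chromosome 19 from 48958239 to 48958406 (plus) overlapped both, and the adjoining peak on chromosome 19 from 48958407 to 48958606 overlapped a UVA peak only.

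The 2755 shared sites on no control peak were spread over 1922 windows of 100 kb, and the 10 windows with the most held 71 of them (2.58%). The plus-strand window of chromosome 11 from 65100001 to 65200000 held 11 such sites, the most of any window, with 24 UVC, 53 UVA and 45 iCLIP sites and no control site. In the next window, from 65200001 to 65300000, 8 sites were shared among 44 UVC, 48 UVA and 40 iCLIP sites, and the controls held 7 (no UV) and 9 (YFP). The minus-strand window of chromosome 1 from 23600001 to 23700000 had 10 shared sites among 24 UVC, 40 UVA and 18 iCLIP sites. Across the 18801 windows, counted per strand, that held a site in at least 1 list, the number of sites had a Spearman correlation of 0.589 between UVA and iCLIP, 0.516 between UVC and iCLIP and 0.361 between UVC and UVA. Correlations of the PTB lists with the controls lay between 0.106 (UVA with YFP) and 0.235 (UVC with no UV). The controls hold only 2341 and 1080 sites, so most windows held none of them. Their correlations are therefore not comparable with those among the PTB lists. All are correlations across windows, which are not independent replicates.

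**Figure D4:**
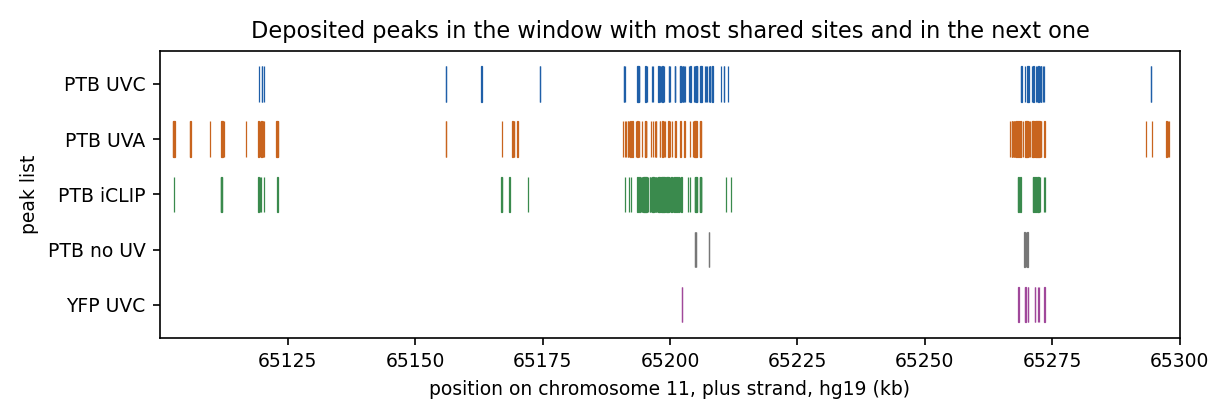
Deposited peaks of the 5 lists on the plus strand of chromosome 11, from 65100001 to 65300000 in hg19 (x axis in kb), each peak drawn as a bar at its position with a line of fixed minimum thickness. The first 100 kb hold 53 UVA sites and no control site, and the next 100 kb hold 7 (no UV) and 9 (YFP) control sites.

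Site widths differed between the lists. Read lengths are not given in the sources used here and the libraries ran on either of 2 platforms, so widths are not read here as the extent of bound regions. In the PTB UVC list 23049 sites (28.6%) were exactly 50 nt wide, as were 1281 sites (54.7%) of the list without UV. In the UVA list 1.22% and in the iCLIP list 1.21% of sites had that width, and the commonest widths were 30 nt and 32 nt. YFP sites were wider, with a median of 87 nt and a commonest width of 142 nt (55 sites). Sites of at most 50 nt made up 83.0% of UVC, 65.0% of UVA, 66.2% of iCLIP, 92.7% of no-UV and 6.30% of YFP sites. The share found in iCLIP rose with width: 4.27% of UVC sites up to 50 nt and 15.9% of wider ones overlapped an iCLIP peak, against 12.3% and 31.4% for UVA. These shares by width were not set against moved copies, and a wider site can meet a peak more easily.

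**Figure D5:**
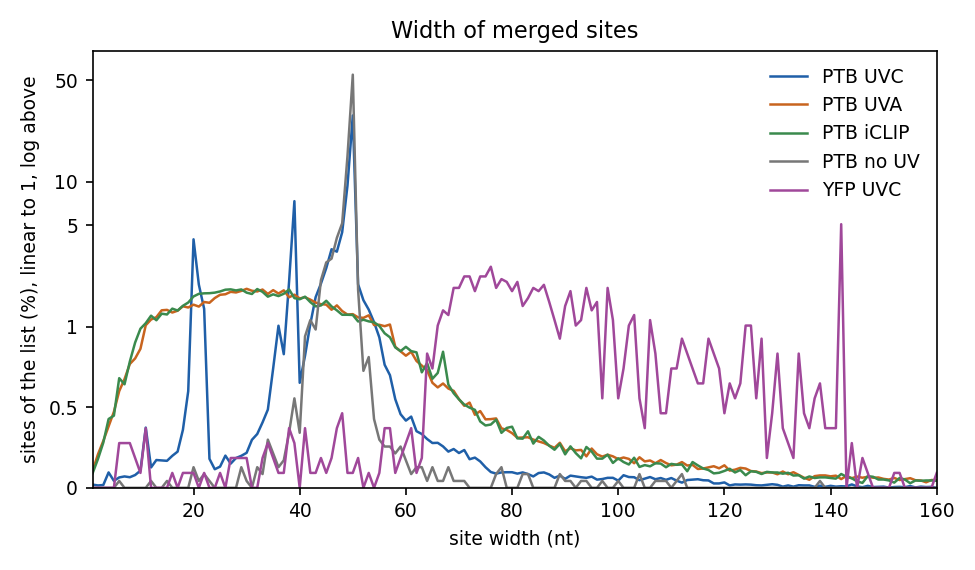
Share of the sites of each list, in percent, by site width in nt after merging peaks within 20 nt. The vertical axis is linear up to 1 and logarithmic above. The UVC and no-UV lists peak at 50 nt (28.6% and 54.7% of sites), and the YFP list at 142 nt.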

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

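Among the alternatives in this section, the limits to scores of at least 100, to sites wider than 50 nt and to peaks outside the controls were added after the main results had been seen. The other alternatives in this section were planned. In all 168 alternative values over the 20 ordered pairs of lists, the observed share stayed above that of moved copies, from 2.22 to 97.1 times. The UVA minus UVC difference in the share found in iCLIP stayed above 0 in 6 alternatives, from 10.7 to 16.9 points. Of 44 alternative values of the 6 planned shares, 16 stayed within the 95% interval, among them all those with strand ignored and with chromosomes 1 to 22 and X only.

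The shares themselves moved with the definition of overlap; apart from what each setting does by construction, the cause was not tested. With at least 50% of the peak covered, the shares were 0.491% of UVC in no UV, 0.557% of UVC in YFP, 0.364% of UVA in no UV, 8.60% of UVA in UVC and 5.48% of iCLIP in UVC. With the peak midpoint within 50 nt of a peak of the second list they were, in the same order, 0.788%, 0.691%, 0.926%, 18.4% and 12.4%. Among peaks at or above the median score they were 0.825%, 1.02%, 0.703%, 16.4% and 10.8%, and 4.54% of no UV in YFP. On merged sites they were 0.518%, 0.348% and 0.484% for the controls and 12.6% for UVA in UVC. With equal numbers of top peaks, 11.5% of UVA and 6.76% of iCLIP peaks were in UVC. Without peaks found in a control these were 13.0% and 9.24%, at scores of at least 100, with 2306 UVC peaks left, they were 3.47% and 2.497%, and among sites wider than 50 nt 12.4% and 7.98%.

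Keeping peaks at or above the median score left, by construction, 60239 UVC, 41979 UVA, 29508 iCLIP, 2138 no-UV and 1195 YFP peaks, covering 2155.13, 1918.54, 1570.4, 57.931 and 50.93 kb. Merging left 2341 no-UV and 1080 YFP sites. No paired analysis was possible because each list pools the replicates of its group, and leaving out each replicate in turn was not run for the same reason. Alternatives fixed beforehand for annotation, motifs, splice sites, gene lists and genes carrying peaks were not run, since no hg19 sequence or annotation was used here. The unknown depth limits every comparison of list sizes and scores.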

Other observations

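Of the tests below, only the one on sites wider than 50 nt was set before its result was seen; the others were chosen after the patterns had been noticed.

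Where GoldCLIP and iCLIP sites lay within 100 nt of each other on the same strand, UVA sites were centred a median of 12 nt downstream of the iCLIP site (16270 sites, 67.0% downstream) and UVC sites 8 nt downstream (7010 sites, 56.7%). UVC sites were centred 8.5 nt upstream of neighbouring UVA sites (12173 sites, 41.3% downstream). Chromosome X carried 11 of the 70 sites found in both controls. Its minus-strand window from 73000001 to 73100000 held the most sites of any window for UVA (62), no UV (33) and YFP (31). The same window held 46 UVC and 6 iCLIP sites, and 0 of the sites shared by the PTB lists on no control peak. The minus-strand window of chromosome 5 from 106900001 to 107000000 held 5 sites without UV, 1 with UVA, 2 with iCLIP and none with UVC or YFP. The minus-strand window of chromosome 18 from 37300001 to 37400000 held 4 YFP sites and none in the other lists.

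Peaks of the PTB UVC list lay more often on the plus strand (61.5%) than those of the UVA list (50.8%), and 62.2% of peaks without UV did too. More binding on plus-strand transcripts is argued against, since only 51.5% of the nucleotides covered by UVC peaks were on the plus strand. After merging within 20 nt, 51.9% of UVC sites were on the plus strand, which is consistent with plus-strand intervals having been divided into pieces during peak calling. Of the UVC peaks 22484 were exactly 11 nt wide, and 19619 of these were on the plus strand.

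A smaller share of UVC than of UVA peaks was found in iCLIP (5.45% against 20.4%). Background was not decided on, because the control lists (3809 and 2136 peaks) are too short to overlap a large part of the 118434 UVC peaks whatever their content. The larger number of low-scoring UVC peaks could account for part of the gap if a score meant the same in both lists, which unknown depth leaves open: with the UVC bands weighted to the UVA scores the share was 17.6% (interval 16.6 to 18.5), closing 81.2% of the gap (interval 74.97 to 87.6), on both sides of the 80% set as the mark of a cause. The bands above 100 carried 47.3% of that weight. In these bands, from 11.9% to 91.1% of UVC peaks lay on a control peak. With the UVA bands weighted to the UVC scores, under the same assumption, the UVA share was 6.21%, closing 94.9%. Among sites wider than 50 nt the UVA share was still 1.97 times the UVC share, which leaves the part of narrow UVC sites open, and a difference in what the wavelengths crosslink stays open and untested.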
